A study of Mus musculus with 18 samples.

How the data were processed

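Each of 3 mouse tissues (colon, small bowel lamina propria, small bowel epithelium) had 3 gene expression libraries and 3 hashtag libraries made from CD45-enriched cells with 5' droplet chemistry, 18 samples in all. Per the labels, KO, het and WT cells carried different hashtags and were pooled before capture, each of the 3 runs used 1 KO, 1 het and 2 WT mice, and the colon preparation combined lamina propria and epithelium. The deposited gene expression values are raw UMI counts per gene and cell, with no normalization, and the deposited hashtag values are raw UMI counts per hashtag and cell. The other deposited values, with a unit recorded as other, are names of genes, hashtags and cell barcodes. Per the submitters the authors used Cell Ranger and Seurat with mm10, and versions are not stated.

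Each tissue's deposited matrix held 9 barcode endings. The hashtag medians showed that an ending marks a library together with a hashtag call of the authors. An ending had been assumed to mark the library alone. Endings of the same capture cannot share a cell barcode, and a single split of the 9 endings into 3 sets of 3 left none shared. Within these sets 0 barcodes were shared, with 66.9 expected by chance in the colon, 69.3 in the lamina propria and 41.4 in the epithelium. The 9 endings were therefore read as 3 libraries of 3 genotypes. Libraries of different tissues were not paired because barcodes carry no run label. The study's filters were applied (200 to 8000 genes, 300 to 50000 molecules, under 20% mitochondrial counts). They removed 401 colon, 253 lamina propria and 280 epithelium cells, each for mitochondrial content.

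Choices of tests, groups, lists and repeats under other settings were made before the data were examined. By that plan a cell's genotype came from HTODemux (Seurat 5.3.0, positive quantile 0.99) unless it left under 40% of any library as singlets. It left 27.22% in lamina propria library 3, so the planned fallback was used: the top hashtag holds at least 80% of a cell's hashtag molecules and at least 10 molecules. HTODemux and the deposited assignment by barcode ending became alternatives. Counts of KO against WT under the deposited assignment, and a table of Il17a, Ifng, Foxp3 and St8sia6 by ending, had been seen before this fallback was put in place and before tests on simulated data. The added alternatives and the choice of what is printed beside each result were therefore made after seeing data. Scrublet marked 4 cells in all (at most 0.05% of a library), under the planned 0.5%, so doublet removal did not work by that tool. The share rule left 33.86% to 79.04% of cells per library. In colon libraries 1 to 3 it left 33.86%, 46.21% and 44.66%, where HTODemux left 88.75%, 82.37% and 78.28%. Colon library 1 thus fell under the 40% that was set for HTODemux. The share rule left more cells than HTODemux in lamina propria libraries 2 and 3 and epithelium library 2, and fewer in the others.

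Cells of all tissues were log-normalised and clustered without integration in scanpy 1.11.5 (python 3.11.15, leidenalg 0.10.2, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3), with 2000 variable genes without receptor variable genes, 30 components, 15 neighbours and resolution 1.5. T cell and myeloid groups were clustered again with 20 components and resolution 1.0. The resulting 44 clusters and 29 sub-clusters were named X-like from fixed markers and their leading genes. Clusters T0, T3, T4, T8, T10 and T13, 8, 35, 36 and M7 kept a number because their leading genes did not settle a name, and clusters with markers of several lineages were called mixed. The marker check was loosened for a short time and then restored to its first form. No unmixing of free RNA was done, and its level is shown by Igha, Igkc, Jchain, Epcam, Fabp1 and Lyz2.

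Counts were summed per genotype, library and class, leaving out sums of under 10 cells. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood F test) with KO, het and WT in 1 fit and the library as a block, since all 3 genotypes of a library shared a capture. Benjamini-Hochberg adjusted p under 0.05 counted as a call. The interaction of genotype and tissue was an F test over the 3 tissues. Cell numbers per class were tested with edgeR against total cells. Beside them stand two-sided exact permutation tests of shares, which regroup across libraries without the pairing and whose smallest p is 0.1 for 3 against 3. Of 24 fixed gene lists, those with at least 5 tested members were tested with camera (limma 3.58.1, correlation 0.01), and again with an estimated correlation and with fry. Printed CPM values are TMM-scaled unless called raw, with SD over libraries. Positions are from GRCm38.p6. Figures were drawn with matplotlib 3.10.9. To test recovery, counts were simulated from a negative binomial law with the means, library sizes and spread of the real sums and an assumed library effect. Changes were planted in these counts, in the epithelium only among the most expressed of the tested genes. For CD4 T-like cells edgeR recovered 99% of genes changed by 2 log2 units in the epithelium, 67.4% in the lamina propria and 74.5% in the colon.

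The within-library pairing rests on the barcode sets above and on the protocol, by which the genotypes were pooled before capture. Mean correlation of centred sums within a library was 0.209, 0.088 and -0.062 in colon libraries 1 to 3, 0.033, 0.181 and 0.135 in the lamina propria, and 0.135, 0.17 and 0.192 in the epithelium. KO and het were both compared with the same WT sums. In simulations with no true difference, 10 in number, the KO and het effects of CD4 T-like epithelium cells correlated at 0.757, against 0.803 measured.

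Named genes followed a rule fixed in advance: St8sia6 everywhere, the 10 higher and 10 lower called genes with the smallest p and the same direction in all libraries (5 and 5 outside CD4 T cells and in all-cell sums), and up to 4 members with the smallest p of each list described. In CD4 T cells Ifng, Tbx21, Cxcr3, Tnf, Il2, Gzmb, Csf2, Il17a, Il17f, Il22, Il23r, Ccr6, Foxp3 and Il10 were added, as were the 6 free-RNA genes above. From these the text prints a selection, and some items are not reported here. Receptor and immunoglobulin variable genes were tested and not named. Genes outside the rule are said to be chosen after their values were seen.

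Results were repeated, as fixed in advance, with RLE size factors, DESeq2 1.42.0, no filter on low counts, no library block, leaving out each library, keeping Scrublet doublets, under 10% mitochondrial counts, KO against the mean of het and WT, a per-cell CD4 gate, TMM factors over classes, and the set tests above. The gate needed a molecule of Cd3e, Cd3d or Cd3g and of Cd4, and none of Cd8a, Cd8b1, Trdc, Cd79a or Lyz2. HTODemux, the deposited assignment, removal of the top 5% of Scrublet scores, and adding clusters T0, T3, T4, T8 and T10 to the CD4 T cells were chosen after seeing the data. Il17a was singled out after its molecule counts per set were seen, and the fixed genes were then tested in the gate and in the wider set under all 3 assignments in all 3 tissues, 18 fits in all. The bounds for reading the Rps18 levels were written after the levels of all 9 libraries had been printed. A Poisson share of at least 90%, fixed in advance to speak against a single carrier mouse, was read that way only where the share within 1 class was also at least 90%, a condition added after the values were seen. The clusters of natural intraepithelial T-like cells of the epithelium were fitted one by one after the values of the class were seen. Raw sequence reads were not used here.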

Results

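Droplet-based single-cell RNA and hashtag counts were collected from CD45-enriched cells of mouse colon, small bowel lamina propria and small bowel epithelium. The mice were St8sia6 knockout (KO), heterozygous (het) or wild type (WT), and per the labels each of the 3 runs used 1 KO, 1 het and 2 WT mice. St8sia6 encodes a sialyltransferase, an enzyme that adds sialic acid to glycans. The series held 18 samples, 9 gene expression libraries and 9 hashtag libraries, with 3 libraries of each kind per tissue, and hashtags separated the genotypes within a library. The deposited matrices held 21687 colon cells, 21600 lamina propria cells and 16985 epithelium cells with 191560456, 158556738 and 99383902 molecules. After filtering, 21286, 21347 and 16705 cells remained. Counts were summed per genotype, library and cell class, so each genotype had n = 3 sums per tissue, and the all-cell sums held 5145114 to 16746980 molecules in the colon, 5942150 to 17601019 in the lamina propria and 3811890 to 15566136 in the epithelium.

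The genotype came from the hashtag share of each cell, which kept 33.86% to 79.04% of cells per library and removed cells unevenly. Of colon B-like cells it kept 1.15% in KO, 10.32% in WT and 65.77% in het mice. Values under the deposited assignment, which uses every cell, are therefore given for many of the counts and shares below. In lamina propria library 3 the WT hashtag led in only 55.48% of the cells assigned to WT, and these cells had a median of 1420 molecules and 507 genes.

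The first question was whether the St8sia6 transcript (ENSMUSG00000003418.11, GRCm38.p6 chromosome 2, 13651018 to 13794734) followed the genotype. In all-cell sums of the small bowel lamina propria it measured 27.3 ± 1.75 CPM (TMM-scaled, SD, n = 3) in KO, 42.9 ± 5.26 in het and 64.5 ± 4.06 in WT. The log2 ratio of KO to WT was -1.24 (SE 0.07, edgeR adjusted p 0.00408, lower in 3 of 3 libraries). Under the deposited assignment the ratio was -0.91 and under HTODemux -0.98, and it no longer passed the threshold in either, nor without library 2 (-1.20). In the colon St8sia6 measured 10.5 ± 2.08 CPM in KO, 12.3 in het and 17.1 ± 3.89 in WT (log2 -0.73, SE 0.26, edgeR adjusted p 0.455). In the small bowel epithelium it was near the detection limit at 2.2 ± 1.62 CPM in KO, 5.26 in het and 3.05 ± 1.71 in WT (log2 -0.24, edgeR adjusted p 0.886). Plasma-like cells carried it in both tissues, and in the lamina propria all-cell sums they were 19.5% of KO and 42.9% of WT cells, so the all-cell ratio mixes this shift with expression. The hashtag share had kept 27.99% of KO and 57.29% of WT plasma-like cells there. Within plasma-like cells it had log2 ratios of -0.88 (SE 0.12, edgeR adjusted p 0.0623) in the lamina propria and -0.96 (SE 0.17, edgeR adjusted p 0.42) in the colon. CD4 T-like cells held too few St8sia6 molecules for a test, with 18 in KO, 16 in het and 12 in WT epithelium cells. Molecules of the gene remained in KO sums, and the labels do not say which part of it was deleted.

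**Figure D1:**
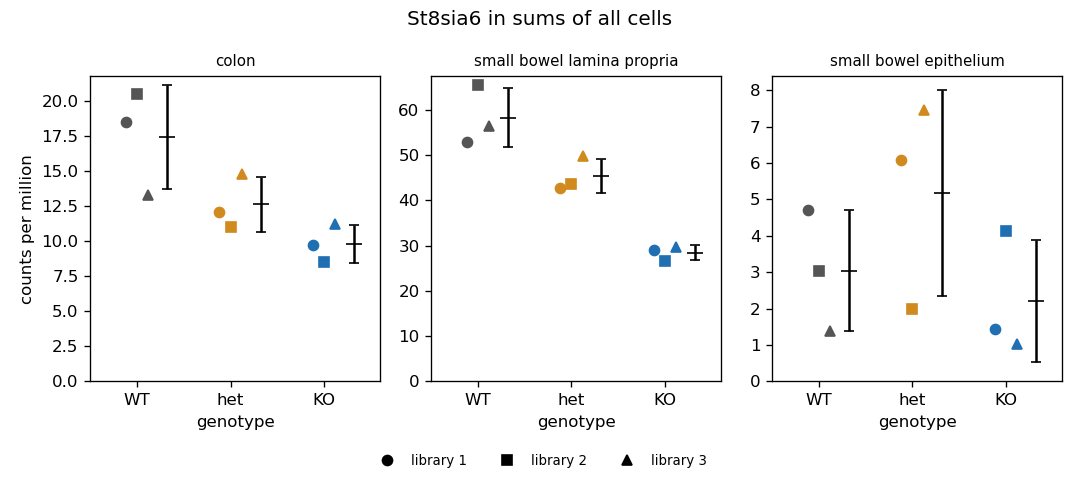
St8sia6 in raw CPM of all cells (y axis) by genotype in the colon, the small bowel lamina propria and the small bowel epithelium. Each point is 1 library and bars give the mean and SD. In the lamina propria KO libraries lie below het libraries, which lie below WT libraries.

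The central comparison asked whether genes differ between KO and WT CD4 T cells, whose Th1 and Th17 programs the series title names. The tested sums of the CD4 T-like class held 457 KO, 1320 het and 198 WT cells in the small bowel epithelium, 103, 99 and 46 in the lamina propria and 41, 76 and 84 in the colon. Sums of under 10 cells are not in these numbers, which left 2 KO sums in the colon and 2 WT sums in the lamina propria. In the epithelium 95.2% of the KO class and 82.8% of the WT class came from a cluster in which 68.3% of cells had a Cd4 molecule and 76.2% a Cd8a molecule (median 4780 molecules per cell). In the largest B-like cluster, which should lack both, the shares were 0.2% and 0.7% (median 3763). That cluster was mostly colon cells (7159 of 7641), so it says little about free RNA in the epithelium. In epithelial-like cluster 39, almost wholly from the epithelium (266 of 268 cells), the shares were 2.2% and 12.3% (median 6538).

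In epithelial CD4 T-like cells edgeR called 11 of 7601 genes, 1 higher and 10 lower in KO. The insulin-degrading enzyme gene Ide (chromosome 19, 37268743 to 37334544) was higher, at 106 ± 8.97 CPM in KO, 78.6 in het and 41 ± 4.07 in WT (log2 1.26, SE 0.23, edgeR adjusted p 0.0383, 3 of 3 libraries). Among the lower genes, the naive-cell gene Igfbp4 fell by 4.21 on the log2 scale (SE 0.68, edgeR adjusted p 0.0207) and Ltb by 0.87 (SE 0.16, edgeR adjusted p 0.0417). The heat-shock genes Hspa1b (-4.45, edgeR adjusted p 0.000711), Hspa1a (-4.19, 0.0207) and Dnajb1 (-1.06, 0.0383) were also lower, as were H2-Q2 (-3.04, 0.0383) and Mtus1 (-3.57, 0.0383). The Rps18 pseudogene Gm10260 had the largest change, at 3.66 ± 0.82 CPM in KO, 10.8 in het and 758 ± 315 in WT (log2 -7.71, SE 0.31, edgeR adjusted p 1.69e-10). At Gm10260, Hspa1b, Hspa1a, H2-Q2, Mtus1 and Ltb the het mean lay nearer to KO than to WT, and 5 of the 10 lower genes were also called lower in het. The remaining lower genes were T cell receptor variable genes. The count was 4 without library 1, 4 without library 2 and 114 without library 3, and 9 with 1 up and 8 down under the deposited assignment, where Igfbp4 (-1.87) and Ltb (-0.67) no longer passed. Ide did not pass without library 1 (1.16, edgeR adjusted p 0.555) or library 2 (1.25, 0.367), under HTODemux (0.94, 0.75), in gated cells (0.82, 0.653), without the top 5% of Scrublet scores (1.28, 0.0649) or for KO against the mean of het and WT (0.82, 0.0752).

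In CD4 T-like cells of the small bowel lamina propria edgeR called 7 of 1611 genes, 4 higher and 3 lower in KO. The chemokine gene Xcl1 measured 555 ± 449 CPM in KO (n = 3), 173 in het and 123 ± 2.63 in WT (n = 2), a log2 ratio of 2.81 (SE 0.56, edgeR adjusted p 0.00419, 2 of 2 libraries). The granzyme gene Gzma (log2 1.48, SE 0.35, edgeR adjusted p 0.0209) and Actb (1.16, SE 0.26, 0.0122) were higher too. Gm10260 was lower (-6.41, SE 1.36, edgeR adjusted p 0.00856), and the others were immunoglobulin variable genes. Plasma-cell RNA was abundant in these sums, with Igha at 13700 ± 7820 CPM in KO and 9860 ± 3080 in WT. DESeq2 called 0 genes here, the deposited assignment gave 8 with 4 higher and 4 lower, and HTODemux reversed Gzma (-0.22). In gated cells 1 gene was called, Il17a, so none of the genes named above was called there. Without the library block 1 gene was called, which was lower in KO. The count was 13 without library 1, 35 without library 2 and 3 without library 3.

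In CD4 T-like cells of the colon edgeR called 0 of 1999 genes, with 69 at an unadjusted p under 0.05, and DESeq2 also called 0. In simulated data of this size edgeR recovered 74.5% of genes changed by 2 log2 units and 17.8% of those changed by 1. The count was 0 without library 1, 8 without library 2 and 2 without library 3.

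The genes fixed in advance by name, such as Ifng and Gzmb, were compared one by one in the CD4 T-like class. None of those tested passed the adjusted threshold, while 1 other member of the Th1 list did in the lamina propria. In the epithelium Ifng measured 334 ± 53.3 CPM in KO, 287 in het and 165 ± 83.8 in WT (log2 0.99, SE 0.29, edgeR adjusted p 0.33, higher in 3 of 3 libraries). Gzmb was likewise higher there in 3 of 3 libraries (4410 ± 193 against 2780 ± 1460 CPM, log2 0.71, SE 0.23, edgeR adjusted p 0.393), as was Tnf (1.00, SE 0.50, 0.618). Il23r was lower in 3 of 3 (-2.36, SE 0.73, edgeR adjusted p 0.362), with 5.22 CPM in KO and 26.8 in WT. Cxcr3 (-0.50), Tbx21 (0.11) and Il10 (-0.30) had edgeR adjusted p of 0.69, 0.954 and 0.948. In the lamina propria Ifng was -1.74 (SE 0.66, edgeR adjusted p 0.331), Gzmb 0.87 (SE 0.45, 0.531) and Tbx21 0.22 (SE 0.85, 0.953). These directions were not stable, with Ifng at 0.63 without library 2 and 0.18 in gated cells, and Gzmb at -2.71 under HTODemux and -0.09 under the deposited assignment. In the colon Ifng was -1.24, Tbx21 0.23, Cxcr3 0.69, Tnf -1.75, Gzmb -0.86 and Il22 -1.88, each with an edgeR adjusted p of 1. Il17a, Il17f, Csf2, Il2, Ccr6 and Foxp3 had too few molecules in this class to be tested in any tissue.

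Gene lists asked whether the Th1 and Th17 programs moved as sets. In CD4 T-like cells of the small bowel epithelium the Th1 list was higher in KO (camera adjusted p 0.00325, 18 of 20 genes higher, median log2 0.31), but not with an estimated correlation (0.448) or with fry (0.183). It was led by Ccl5 (0.73), Ifng, Gzmb and Hopx (0.50). Of its genes 2 passed when adjusted over the list alone and 0 over all genes tested. The Th17 list there had an adjusted p of 0.602 (6 of 10 higher) and the pathogenic Th17 list 0.202 (10 of 11 higher). The naive and recirculating list was lower in KO (1.21e-08, and 0.448 with an estimated correlation, 0 of 11 higher, median -2.35), with Igfbp4, Lef1 (-2.72), Klf2 (-2.35) and Ccr7 (-3.35) leading. Of its genes 9 passed when adjusted over the list alone and 1 over all genes. The cytotoxic (0.000797, 12 of 14 higher) and proliferation lists (0.000797, 9 of 9 higher) were higher, and the dissociation stress list was lower (0.000869, 5 of 20 higher). With an estimated correlation these gave 0.458, 0.448 and 0.317. Cluster T9 of this class, led by Lef1, Igfbp4 and Tcf7, made up 2.4% of it in KO and 12.1% in WT. The plasma secretory list was higher and the TGF beta list lower at 0.0497 each. For the Th1 list the adjusted p was 0.148 without library 2 and 0.261 under the deposited assignment. With an estimated correlation 0 of the list calls in any tissue passed the threshold.

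In the small bowel lamina propria the Th1 list (camera adjusted p 0.931, 8 of 16 genes higher) and the Th17 list (0.931, 3 of 7 higher) were not called between KO and WT CD4 T-like cells. Of the Th1 genes there, 1 passed over all genes tested and 4 when adjusted over the list alone. No list call in this paragraph passed with an estimated correlation. The oxidative phosphorylation list was higher in KO (0.000139, and 0.949 with an estimated correlation, 21 of 24 higher, median 0.54), with Atp5b (1.68), Cox5b (1.11) and Ndufa4 (1.11) leading. In the colon the Th17 list was lower in KO (0.0293, 2 of 11 higher, median -0.33), with Irf4 (-2.12) and Furin (-0.78) leading, and the Th1 list had an adjusted p of 0.074 (8 of 18 higher). The colon activation list was lower (0.0293, 5 of 16 higher), while the stress (0.0293, 17 of 20) and type I interferon lists (0.0363, 4 of 6, Isg15 1.78) were higher. The colon Th17 call was lost without library 1 (camera adjusted p 0.062), without the library block (0.0746), under HTODemux (0.927) and under the deposited assignment (0.755). Its direction reversed without library 3 and with clusters T0, T3, T4, T8 and T10 added (0.732). Clusters T8 and T3, both led by Il17a, were outside the tested class. With the clusters added, T8 was 14% of KO and 7.3% of WT cells in the colon. T3 was 38.4% of both in the lamina propria. The Th17 tests of the CD4 T-like class therefore do not speak for all CD4 T cells.

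Th17 cytokine transcripts lay mainly outside the CD4 T-like class, in clusters whose leading genes matched several marker lists. A planned per-cell gate for Cd3 and Cd4 took in part of these cells. A Cd4 molecule was present in 47.2% of cluster T3 cells. The gate left out cells with Cd79a, found in 96% of mixed cluster 12, which also had Il17a among its leading genes. The Il17a values given next were singled out after its molecule counts had been seen. In gated lamina propria cells Il17a measured 1040 ± 500 CPM in KO (n = 3), 1420 ± 824 in het (n = 3) and 88.1 ± 46.2 in WT (n = 2). The log2 ratio was 3.25 for KO (SE 0.33, edgeR adjusted p 0.00662, higher in 2 of 2 libraries) and 3.60 for het (edgeR adjusted p 0.00283). Under the deposited assignment it was 0.28 (SE 0.67, edgeR adjusted p 0.979), and under HTODemux 2.67, with a single KO sum and so no spread within KO. The call was lost without library 2 (3.08, edgeR adjusted p 0.444). With clusters T0, T3, T4, T8 and T10 added to the class, Il17a was 3.18 (SE 0.30, edgeR adjusted p 3.66e-07, 3 of 3 libraries), and 1.83 (SE 0.62, edgeR adjusted p 0.278) under the deposited assignment. In that wider set the epithelium gave 1.48 (SE 0.91, edgeR adjusted p 0.588) and the colon 0.87 (SE 0.29, edgeR adjusted p 0.893). Single libraries decided both, since the epithelium gave -0.70 without library 1 and 5.95 (edgeR adjusted p 0.032) without library 3, and the colon 1.24 (edgeR adjusted p 0.0103) without library 2 and 0.25 without library 3.

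Lists were tested in the gated cells too, where the Th17 list had 15, 18 and 13 tested members in the lamina propria, colon and epithelium against 7, 11 and 10 in the CD4 T-like class. The Th17 list was higher in KO in the small bowel lamina propria (camera adjusted p 0.000463, and 0.961 with an estimated correlation) and in the small bowel epithelium (0.035, and 0.538), and in the colon it was 0.064 and higher. In the epithelium the Th1 list was higher in the gated cells as well (5.25e-10), also under the deposited assignment (1.23e-09) and HTODemux (8.46e-06). For the Th17 list the deposited assignment gave 0.142 in the lamina propria, 0.000998 in the epithelium and 0.026 in the colon, higher in each, where the CD4 T-like class had given a lower Th17 list in the colon. The colon Th1 list was higher in gated cells under the deposited assignment (0.00296) and HTODemux (0.00726) but not called under the hashtag share (0.849). The gated lists under other assignments were run after the first values were seen. With an estimated correlation the smallest p among the gated-cell lists was 0.259.

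The interaction test asked whether the KO effect in CD4 T-like cells differs between tissues, and edgeR called 0 of 2947 genes, with 237 at an unadjusted p under 0.05. The smallest-p Th1 genes were Ifng (p 0.0213, edgeR adjusted 0.587), Tnf (p 0.0292, 0.595) and Cxcr3 (p 0.0428, 0.595). With the deposited assignment 1 gene was called and with the clusters added 8. In simulated data this test recovered 35.5% of genes changed by 2 log2 units. The simulation gave all genes the same spread and all tissues the same mean levels, without a library effect. It planted the change only in the epithelium, so recovery of a change in the colon or the lamina propria was not tried.

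The het comparison asked where the intermediate genotype lies. Against WT, edgeR called 5 genes in epithelial CD4 T-like cells, 3 in the lamina propria and 0 in the colon, where 75 had an unadjusted p under 0.05. These genes were named after their values were seen. In the epithelium Gm10260 (-6.63), Hspa1b (-3.65), Hspa1a (-3.69), Ltb (-0.99) and a receptor variable gene were lower in het, and in the lamina propria Gzma was higher (1.56, edgeR adjusted p 0.0161) and Gm10260 lower (-6.02). KO against het gave 0 genes in epithelial CD4 T-like cells, with 338 at an unadjusted p under 0.05.

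All-cell sums asked what changes without clustering, mixing composition and expression. In the colon edgeR called 8 of 14519 genes, each higher in KO, including the myeloid genes Cxcl16 (1.17), C5ar1 (1.57) and Pla2g7 (0.99) and the transcripts Gm42031 (1.59) and Gm46620 (1.77). In the lamina propria it called 866 genes, 529 higher and 337 lower. Nr2f2 (1.57, edgeR adjusted p 0.00408) and Selp (1.96, 0.00736, and -0.13 under HTODemux) were higher, as was Lyz2 (0.90, 0.0151), while St8sia6, Fhod3 (-1.45), Chac1 (-1.21) and Igkc (-0.55, 0.0421) were lower. In the epithelium it called 2210 genes, 728 higher and 1482 lower, with Epcam (-1.69, 0.00617), Fabp1 (-1.36, 0.0133), Tff3 (-2.01) and App (-1.79) lower and Ide (0.79, 0.00383) and Arhgap10 (0.84) higher. Under the deposited assignment the counts were 0 in the colon, 0 in the lamina propria and 4181 in the epithelium, and DESeq2 called 232 genes in the colon. KO against het called 1 gene in the colon, 88 in the lamina propria and 0 in the epithelium, where 1575 had an unadjusted p under 0.05. The count fell to 0 in the colon without any 1 library and to 69, 19 and 26 in the lamina propria without libraries 1, 2 and 3. In the epithelium it was 397, 518 and 981.

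Cell composition was compared to ask which populations change with genotype. In the epithelium CD4 T-like cells made up 12.6% ± 0.21 of KO cells, 19.9% ± 12.7 of het cells and 5.44% ± 0.753 of WT cells (SD, n = 3, log2 1.19, edgeR adjusted p 0.0163, exact permutation p 0.1, higher in 3 of 3 libraries). The deposited assignment gave 12.3% in KO and 3.63% in WT. Epithelial-like cells fell from 4.10% ± 1.12 in WT to 0.643% ± 0.389 in KO (log2 -2.68, edgeR adjusted p 0.000847), and cluster 8, T cells with natural-killer receptor genes, rose from 1.10% to 5.62% (2.28, edgeR adjusted p 0.0107). In the lamina propria Treg-like cells were 1.90% ± 0.65 in KO, 0.883% in het and 0.671% ± 0.366 in WT (1.66, edgeR adjusted p 0.0164, exact permutation p 0.1), and 1.41% and 0.305% in KO and WT under the deposited assignment. NK or ILC1-like cells (2.08% against 0.634%, 1.66, edgeR adjusted p 0.00565), fibroblast-like (1.71, 0.0176), endothelial-like (1.41, 0.0151) and macrophage-like cells (0.79, 0.0437) also rose there. The CD4 T-like (1.17, edgeR adjusted p 0.0437) and unresolved T cell-like classes (0.96, 0.0403) and the Il17a-rich cluster T3 (1.99% against 0.853%, 1.36, edgeR adjusted p 0.0477, exact permutation p 0.3) rose as well. Because the cells were CD45-enriched, the epithelial-like, fibroblast-like and endothelial-like shares do not measure how much of these cells a tissue held. With TMM factors over classes 0 lamina propria classes were called higher (4 at an unadjusted p under 0.05), so each rise there rests on scaling by total cells. Calls for epithelial CD4 T-like cells, epithelial-like cells, cluster 8, Treg-like cells, NK or ILC1-like cells and cluster T3 were also made under the deposited assignment and HTODemux. Under the deposited assignment, clusters of few molecules took up a larger share of WT than of KO cells in both small bowel tissues. This lowers the WT shares of all other classes there. Without library 1 or library 2 no lamina propria class passed, nor did epithelial CD4 T-like cells (0.171 and 0.264) or cluster 8 of the epithelium (0.182 and 0.0859), and without library 1 epithelial-like cells did not either (0.135). The exact permutation tests did not keep the library pairs, and with 3 against 3 they cannot go below 0.1. Mixed clusters held 23.8% of KO and 16% of WT colon cells and 23.6% and 13.6% of lamina propria cells.

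Plasma-like cells in the lamina propria (19.5% ± 9.29 in KO against 42.9% ± 4 in WT, log2 -1.23, edgeR adjusted p 0.0164) and B-like cells in the colon (1.44% ± 1.57 against 8.84% ± 9.47, -2.51, 2.61e-05) and the epithelium (-4.62, 5.94e-06) were lower in KO under the hashtag share. None of the 3 was called under the deposited assignment, where plasma-like cells were 34.4% and 35.3% and colon B-like cells 33% and 38.6%.

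**Figure D2:**
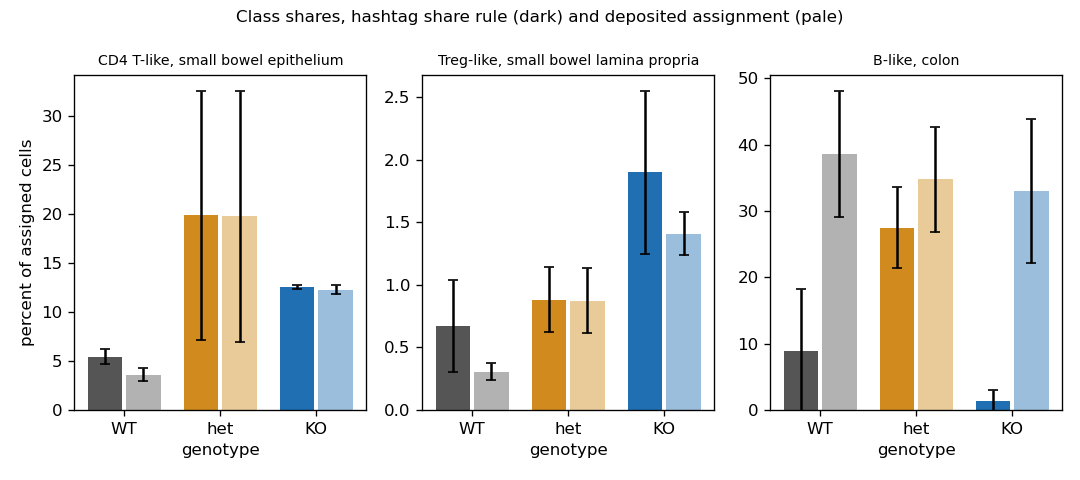
Share of cells in percent (y axis) by genotype for CD4 T-like cells of the small bowel epithelium, Treg-like cells of the small bowel lamina propria and B-like cells of the colon, under the hashtag share (dark) and the deposited assignment (pale). Bars give the mean and SD over 3 libraries. The KO and WT means of the epithelium and lamina propria classes keep their order under both, while the colon B-like share changes with the assignment.

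Other classes asked whether the KO effect reaches innate and intraepithelial cells, and 630 genes were called over 14 tests of a class in a tissue, 347 higher and 283 lower, or 251 with all 97684 tests adjusted together. In ILC3-like cells of the lamina propria (20 genes) Il22 rose from 2130 ± 584 CPM in WT and 3580 in het to 5630 ± 2590 in KO (log2 1.34, SE 0.17, edgeR adjusted p 0.000476, 3 of 3 libraries), while Jun (-1.09), Fos (-0.89) and Smad3 (-1.26) were lower. Cd3e (2.29) and Cd3d (2.26) were higher in the same sums, and under the deposited assignment Il22 was 0.64 and not called. ILC2-like cells (83 genes, and 19 with all classes adjusted together) had higher Satb1 (2.08, edgeR adjusted p 0.00632), Tgm2 (3.85) and Ccl1 (3.23) and lower Zeb2 (-2.71, 0.00996) and Prickle1 (-5.02). Unresolved T cell-like cells of the lamina propria (9 genes) had higher Ccl5 (0.68, SE 0.07, edgeR adjusted p 1.35e-05), Gzma (0.63) and Nr4a3 (1.15) and lower Zbtb16 (-2.12, SE 0.24, 3.84e-05), which encodes PLZF. Lamina propria epithelial-like cells (13 genes) had lower Fabp6 (-4.53), Itln1 (-4.37) and Lgr5 (-1.55), and Itln1 reversed under the deposited assignment (0.44). Plasma-like cells had 2 called genes, including Gm42031 (1.82).

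Among epithelial T cells, natural intraepithelial T-like cells (192 genes, and 95 with all classes adjusted together) had higher Ccl5 (27300 ± 1850 against 16400 ± 956 CPM, log2 0.73, SE 0.06, edgeR adjusted p 2.61e-07) and Gzma (0.45, SE 0.06, 7.47e-05) in KO, with het at 24200 and 24100 CPM. Xcl1 was lower in these cells (-1.32, SE 0.13, edgeR adjusted p 3.41e-06), with 179 ± 57.5 CPM in KO, 284 in het and 453 ± 7.63 in WT. Ide was higher in them (0.72) and in gamma-delta T-like cells (0.79, 24 genes), where Il31ra was lower (-0.70, edgeR adjusted p 0.000387). The class joins clusters 3 and 7, and cluster 3, in which Gzma is a leading gene, made up 76.8% ± 5 of it in KO, 76% in het and 59.7% ± 2.3 in WT (SD, n = 3), while Xcl1 leads cluster 7. Fits within each cluster, run after these values were seen, called Ccl5 (0.45, edgeR adjusted p 0.00143) and Ide (0.65, 0.0041) in cluster 3 but not in cluster 7 (0.15, 0.616 and 0.36, 0.664). They called Gzma (1.31, 0.000218) and Xcl1 (-0.72, 4.61e-05) in cluster 7 but not in cluster 3 (0.07, edgeR adjusted p 0.8 and -0.93, 0.191). For the whole class these Ccl5, Gzma, Xcl1 and natural intraepithelial Ide calls were also made without each library in turn and under the deposited assignment and HTODemux. CD8 alpha-beta T-like cells (43 genes) had higher Rps18 (0.52, edgeR adjusted p 0.00253) and Nr4a2 (0.53) and lower H2-D1 (-0.55). Unresolved epithelial T cell-like cells (235 genes) had lower Tox (-1.33) and Ikzf2 (-1.69), and 9 of its genes were called with all classes adjusted together. In the colon natural intraepithelial T-like cells (5 genes) had higher Gadd45g (2.34, edgeR adjusted p 0.00249) and Klra1 (1.57) and lower Trat1 (-1.14), and epithelial-like cells had lower Ang4 (-7.83). Colon plasma-like cells had 3 called genes, and colon cluster 8 and NK or ILC1-like cells had 0, with 528 and 140 at an unadjusted p under 0.05.

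Gm10260 (ENSMUSG00000069117.4, chromosome 13, 97760087 to 97760609) separated WT from KO and het sums in most classes but not in all libraries. In all-cell sums its raw WT level was 604.95, 640.14 and 409.43 CPM in the 3 epithelium libraries, 166.2, 302.19 and 3.87 in the lamina propria and 0.9, 622.92 and 1.9 in the colon. KO sums lay between 0.29 and 13.2 CPM. Hspa1b (chromosome 17, 34956429 to 34959238), Hspa1a, Ltb, Tnf, H2-D1 and H2-Q2 lie near Rps18 (chromosome 17, 33951998 to 33955665), the parent gene of this pseudogene.

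**Figure D3:**
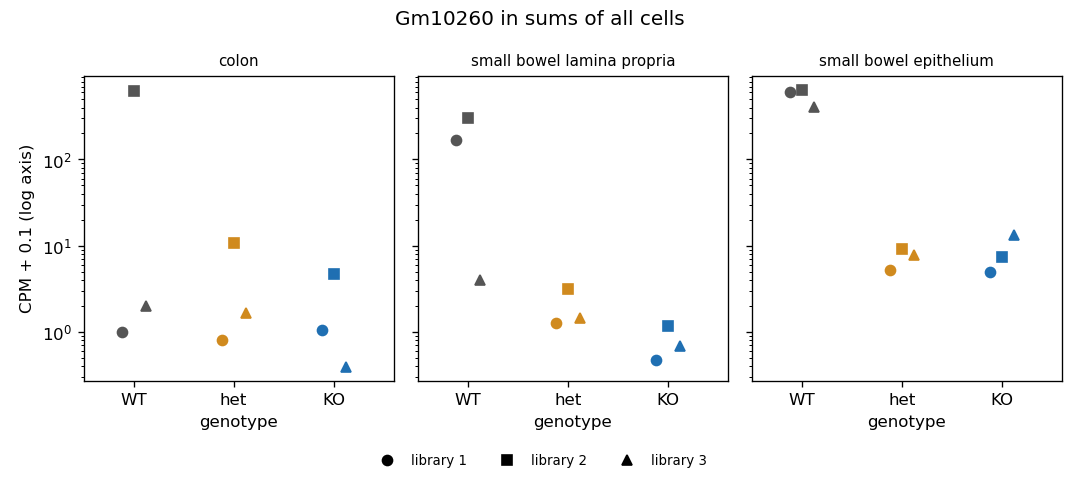
Gm10260 in raw CPM plus 0.1 (log y axis) in all-cell sums by genotype and tissue. Each point is 1 library. All 3 WT libraries of the epithelium, 2 of the lamina propria and 1 of the colon lie above 50 CPM, and no KO or het library does.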

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

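Of the tests given here, those of WT mice carrying the difference singly, of epithelial cells and few-molecule barcodes, of regrouped samples, of the interaction and of the per-cell gate were fixed before their results were seen, and the other tests were chosen only after the result was seen.

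In CD4 T-like cells Cxcr3 was higher in KO in both usable colon libraries (log2 0.69) and lower in all 3 epithelium libraries (-0.5), and Tnf was higher in the epithelium (1.0) and lower in the colon (-1.75). These opposite directions drew attention, and the difference itself was tested over the 3 tissues with an interaction term. It did not pass after adjustment for Tnf (p 0.0292, edgeR adjusted 0.595) or Cxcr3 (p 0.0428, edgeR adjusted 0.595). The colon side rests on 41 KO cells, and under the per-cell gate Cxcr3 was 0.7 in the epithelium and Tnf 0.4 in the colon, both reversed. No group held enough samples to look for single outlying samples.

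Gm10260 exceeded 50 CPM in the WT sum, but not in the KO or het sum, of 6 of the 9 libraries. H2-Q2 averaged 52.45 ± 16.81 raw CPM in WT and 11.17 ± 0.58 in KO all-cell sums of the epithelium (SD, n = 3). It averaged 34.85 ± 34.15 and 12.1 ± 2.18 in the colon, and 6.83 ± 4.32 and 3.59 ± 1.5 in the lamina propria. Whether it followed Gm10260 from library to library was not tested. Genes of the H2 region did not all go the same way. In the later fits of natural intraepithelial T-like clusters 3 and 7 of the epithelium, H2-Q2 was lower in KO (log2 -2.22 and -3.06). H2-Q7 was higher there (0.46 and 0.51). Library depth did not go with the Gm10260 difference (Spearman rho -0.07). A swap of WT with KO or het samples would need a KO or het sum near WT levels, and the highest reached 2.07% of the highest WT sum. That test cannot see a mouse without the transcript that was tagged as WT, so such mislabelling stays open. Rps18 itself was lower in WT in the 6 libraries (median log2 -0.65), while Rps18 and Gm10260 counted together went both ways (0.28, -0.44, -0.25, 0.07, -0.07 and 0.11, median 0). Where WT sums nearly lacked Gm10260, Rps18 was lower in WT in lamina propria library 3 (-0.35) but not in colon libraries 1 (0.05) and 3 (0.56). Reads of Rps18 counted under its pseudogene in mice that carry another Rps18 sequence therefore stay open. A different genetic background of the WT mice stays open: the lowest WT to KO ratio among 61 classes was 0.94, nominally under the bound of 2 set for it, but in low-count classes, and 0 classes had an exact interval below 10 (the interval reading and the 50 CPM level that picked the libraries were chosen after seeing the ratios), while 1 colon library against 3 epithelium libraries carried the transcript although the design names the same mice for all tissues. If only some of the WT mice of a run carried it, cells with a molecule would fall short of the Poisson share, and they reached 69.1% of it in epithelium library 1 and 56.01% in library 3, which may fit a carrier among non-carriers, while 92.85% in colon library 2, 90.5% in lamina propria library 2, 89% in epithelium library 2 and 76.39% in lamina propria library 1 leave it open, since within 1 class of colon library 2 the share was 87.42% against a median of 94.25% for genes of like level (percentile 7, and percentiles 2.4, 13.5 and 1 in epithelium libraries 1 to 3), epithelium library 2 gave 91.01% in that class, and no such class reading was made in the lamina propria, where 90.5% lies close to the bound of 90%. Genes that move with Gm10260, or lie in the same part of chromosome 17, among them Hspa1b, Hspa1a, Ltb, Tnf, H2-D1 and H2-Q2, could therefore differ by background and not by St8sia6.

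B-like cells were a lower share in KO than in WT in the colon and the epithelium under the hashtag share. Under the deposited assignment, which uses every cell, the log2 ratios were -0.23 (SE 0.41) and 0.18 (SE 0.59), and under HTODemux -0.24 (SE 0.49) and -0.07 (SE 0.74). The larger difference is in line with uneven removal of B-like cells by the share rule, and a shared genotype effect of the size called is not seen under either of the other assignments.

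In all-cell sums of the epithelium 2210 genes differed. Without epithelial-like, mixed and unnamed clusters 110 genes were called, so most of the count may come from a different share of epithelial cells and few-molecule barcodes in WT. KO against het gave 0 genes, but het against WT gave only 33 higher and 57 lower. Of these, 29 higher and 57 lower genes were called the same way in KO, which was compared with the same WT sums. The KO and het effects correlated at 0.707, against 0.538 in simulations with no true difference (covariance 0.328 against 0.052). After the exclusion KO against het gave 74 genes and het against WT 48. How far het mice share the difference with KO mice therefore stays open. The same exclusion gave 2426 genes in the lamina propria, against 866 in its full sums, with other classes of differing share left in.

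Regrouping the 3 KO and 3 WT sums gave 10 splits, too few for a share under 0.05. With the real value first and the highest other split second, the CD4 T-like epithelium gave 11 and 19 genes (2 splits as large), colon all-cell sums 8 and 1, lamina propria all-cell sums 866 and 1, and epithelium all-cell sums 2210 and 4 (1 split as large in each of these). Other classes gave 630 and 38 genes, cell classes 1 and 0 in the colon, 9 and 1 in the lamina propria and 4 and 0 in the epithelium, and the Th1 list of the epithelium p 0.00325 and 0.0118, again with 1 split as large. The Th17 list of the epithelium gave 0.602 and 0.0905 (6 splits), het against WT in the epithelium 5 and 36 genes (3 splits) and in the colon 0 and 11 (10 splits). Among the splits that, like the real one, part all 3 library pairs, the highest other count was 0 for CD4 T-like epithelium cells, so its 19 came from splits that leave a pair together, while for het against WT in the epithelium it stayed 36, several times the real count, which may reflect a structure of the sums other than genotype.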

How the results depend on the processing

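HTODemux, the deposited assignment, removal of the top 5% of Scrublet scores and the added clusters are tests chosen after the data were seen, and the others were planned. Results that stayed within the 1.5-fold range or on their side of the threshold numbered 9 of 9 with RLE size factors, 17 of 17 with Scrublet doublets kept, 8 of 9 with under 10% mitochondrial counts, 14 of 18 without the top 5% of Scrublet scores, 10 of 18 with HTODemux, 9 of 18 with the deposited assignment and 7 of 18 without the library block. They numbered 2 of 9 with no filter on low counts, 3 of 9 with the per-cell gate, 4 of 11 with the added clusters, 5 of 16 without library 1, 5 of 16 without library 2 and 7 of 16 without library 3. DESeq2 kept 4 of 7, KO against the mean of het and WT 10 of 16, an estimated correlation 4 of 6, fry 3 of 6 and TMM factors over classes 2 of 3. Keeping Scrublet doublets put back only 4 cells in all, so its 17 of 17 was close to fixed in advance. Named genes kept direction and side of the threshold in 1271 comparisons, were no longer called in 359, became called in 11 and reversed in 28. That setting is among these comparisons. The cause was not tested for the changes below, except where the setting itself removes sums or genes.

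With DESeq2, CD4 T cells gave 0 genes in the small bowel lamina propria and 27 in the epithelium, all cells of the colon 232, and Tbx21 in the lamina propria was 0.00. With no filter on low counts, CD4 T cells gave 22 genes in the colon, 4 in the lamina propria and 120 in the epithelium, all cells of the colon 37, other classes 1747, het against WT 138 and the interaction 24; more genes were tested. With under 10% mitochondrial counts the colon all-cell count was 5.

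Without the library block (no pairing within libraries), CD4 T cells gave 1 gene in the lamina propria and 6 in the epithelium, all cells 1 in the colon and 369 in the lamina propria, other classes 239, the interaction 1, and cell classes 0 in the colon and 4 in the lamina propria. The colon Th17 list had p 0.0746, and in the lamina propria both lists reversed (Th1 0.931, Th17 0.931).

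Against the mean of het and WT, KO CD4 T cells of the epithelium gave 2 genes, all cells 28 in the colon, 486 in the lamina propria and 918 in the epithelium, other classes 276 and epithelium cell classes 2, while Il10 in the epithelium was 0.09 and Tbx21 in the lamina propria -0.31. TMM factors over classes left 1 class in the lamina propria, the lower plasma-like class. An estimated correlation gave 0.43 for the colon Th17 and 0.448 for the epithelium Th1 list. Fry gave 0.567 for the colon Th17 list, 0.183 for the epithelium Th1 list and 0.996, reversed, for the lamina propria Th17 list.

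With the per-cell gate, CD4 T cells gave 1 gene in the lamina propria and 2 in the epithelium. The Th17 list became called and higher in the epithelium (0.035) and reversed to higher in the lamina propria (0.000463) and the colon (0.064), where Th1 reversed too (0.849). With an estimated correlation the gated Th17 list gave 0.538 in the epithelium and 0.961 in the lamina propria. Reversed genes were Cxcr3 in the epithelium (0.7), Il23r in the epithelium (0.42), Gzmb (0.27), Il22 (1.07), Tbx21 (-0.06) and Tnf (0.4) in the colon, and Ifng in the lamina propria (0.18). With clusters T0, T3, T4, T8 and T10 added, CD4 T cells gave 1 gene in the colon and 20 in the epithelium, het against WT 66 and the interaction 8. Reversed values were Th17 in the colon (0.732), Th1 (0.721) and Th17 (0.0117, and 0.349 with an estimated correlation) in the lamina propria and Gzmb in the lamina propria (-0.03).

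With HTODemux, CD4 T cells gave 1 gene in the lamina propria and 3 in the epithelium, all cells 0 in the colon and 1 in the lamina propria, het against WT 5 and lamina propria classes 4. The colon Th17 (0.927) and epithelium Th1 list (0.0903) no longer passed. Reversed genes were Gzma (-0.22) and Gzmb (-2.71) in lamina propria CD4 T cells, Ifitm2 (-0.09) and Selp (-0.13) in lamina propria all-cell sums, St8sia6 in epithelium all-cell sums (0.15), and Tbx21 in the colon (-0.02) and epithelium (-0.16). With the deposited assignment, all cells gave 0 genes in the colon, 0 in the lamina propria and 4181 in the epithelium, the interaction 1 and colon classes 2. The colon Th17 (0.755) and epithelium Th1 lists (0.261) no longer passed, and Th1 reversed in the colon (0.755) and the lamina propria (0.961), as did B-like cells in the epithelium (0.18), Gzmb in lamina propria CD4 T cells (-0.09), and Defa26 (0.22) and Itln1 (0.44) in lamina propria epithelial-like cells. Without the top 5% of Scrublet scores, CD4 T cells gave 11 genes in the lamina propria and 4 in the epithelium, all cells of the colon 1, and the colon Th17 list p 0.066.

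Leaving out 1 library at a time, CD4 T cells gave 0 to 8 genes in the colon, 3 to 35 in the lamina propria and 4 to 114 in the epithelium, where a lone sum of a group is assumed to vary like the others. All cells gave 0 to 0 in the colon, 19 to 69 in the lamina propria and 397 to 981 in the epithelium, other classes 360 to 487, and cell classes 0 to 7 in the lamina propria and 1 to 7 in the epithelium. List p ranged for Th1 from 0.000603 to 0.464 in the colon, 0.431 to 0.997 in the lamina propria and 0.00945 to 0.148 in the epithelium, and for Th17 from 0.000357 to 0.168, 0.556 to 0.997 and 0.271 to 0.861. Log2 ranges that crossed 0 were Gzmb in the colon (-2.97 to 0.25), Ifng in the lamina propria (-2.46 to 0.63), Il10 in the epithelium (-0.83 to 2.14), St8sia6 in epithelium all-cell sums (-1.04 to 0.52), and Tbx21 in the colon (0.00 to 0.35), lamina propria (-0.2 to 0.62) and epithelium (-0.14 to 0.33). The interaction was not run for the mitochondrial limit, the gate or single libraries left out. Few cells and molecules limit the CD4 T-like class: 1999 genes were tested in the colon and 1611 in the lamina propria against 7601 in the epithelium.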

Other observations

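The transcript Gm42031 was higher in KO than in WT libraries of the colon, at 86.88, 106.84 and 54.38 raw CPM against 27.86, 37.44 and 22.74, with het at 33.38, 46.51 and 28.25. The small bowel lamina propria gave 93.91, 109.92 and 46.54 in KO against 17.37, 28.59 and 18.51 in WT. In the epithelium the values were 30.88, 44.72 and 18.58 in KO and 24.14, 21.89 and 23.57 in WT. It was chosen for this paragraph after its values were seen.

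Under the deposited assignment, clusters of few molecules made up 17.3% ± 5.26 of WT epithelium cells (SD, n = 3), 0.878% of KO cells and 1.04% of het cells. In the lamina propria they were 26.2% ± 21.3 of WT and 2.21% of KO cells. Epithelial-like cells of the epithelium were 12.3% ± 5.8 in WT and 2.11% in KO under the same assignment. No explanation was tested for the few-molecule clusters.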
